A study of Malus domestica with 2 samples.

How the data were processed

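Messenger RNA from pedicels, the stalks that carry the fruits of a cluster, was sequenced in apple (Malus domestica, cultivar Saika) on a Roche 454 GS-FLX pyrosequencer, per the labels' protocols. The 2 samples form 2 groups, the central pedicel and the lateral pedicel, with 1 library per group. No difference between the groups therefore has a replicate check, and every test on counts compares these 2 libraries and not the 2 kinds of pedicel.

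The authors deposited a table of 63541 gene models with a count per library, a count of uniquely mapped sequences, and RPKM, the count scaled by gene length and library total. Per the file headers, the counted input was a trimmed set of contigs from each library, so the counted units are called mapped sequences here. The RPKM values deposited by the authors equal the count divided by gene length and library total. A further deposited column, in the sense of TPM, holds RPKM rescaled to a total of 1000000 in each library. The authors' p-value and FDR columns in that table come from Kal's Z-test, per the file headers, and the score of that test is deposited beside them. A pair of sheets headed CP and LP lists differing genes of the central and lateral pedicel found with NOISeq, per the file headers, each entry with a deposited p-value and FDR. A last file holds log2 ratios deposited by the authors for 215 genes, per the file headers lateral over central. Their signs are compared with that stated direction below. The aligner, assembler, read trimming and gene model release are not given in the sources used here. In the deposited table, 11 further columns with values of the libraries were not used.

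Counts were tested per gene model with a two-sided Fisher exact test of its sequences against all other sequences of each library. The Benjamini-Hochberg adjustment ran over gene models with at least 10 sequences summed over both libraries. A gene model was called at an adjusted p under 0.05 and a fold of at least 2 between values scaled by the library total, with 0.5 added to each count. Log2 ratios computed here are lateral over central. Sequences were few, 18483 in the central and 18368 in the lateral library, so 3 sequences, the limit that a count of 0 allows, correspond to 0.0162% and 0.0163% of a library. Intervals are 95% exact Clopper-Pearson intervals. Like these limits, they cover counting error only and take the sequences as independent, which contigs of one transcript are not. A library pair cannot be fitted with edgeR's quasi-likelihood test. Its negative binomial exact test (edgeR 4.0.16 in R 4.3.3) was run with assumed biological coefficients of variation of 0.2 and 0.4.

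The test was tried on simulated data with 200 changed genes among 63541 gene models, equally many higher and lower. At the depth of these libraries it recovered 0% of 4-fold and 48% of 16-fold changes, and at 100 times that depth 100% of both. The changed genes had more than a single sequence over both libraries, and only their lateral counts were changed. At the real depth a lowered gene thus seldom reached 10 sequences, and the recovered share was not split by direction. In these runs 125 and 203 gene models reached 10 sequences, against 24 in the data, so the 48% does not carry over to the data. The simulated sequences were independent of each other, which contigs of one transcript are not.

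Before the data were examined, 35 gene lists were fixed, each a set of words searched in the annotation. Per list, the median log2 ratio was placed among 10000 random lists of the same size matched on mean count in 10 bins. After the data were seen, the lists were also counted on the CP and LP sheets. There the number of LP entries was placed among 10000 random draws of as many annotated genes from both sheets, as a description, since genes are not replicates and no p-value was computed across them. The rule for named genes, also fixed beforehand, took the 10 called gene models of largest log2 ratio in each direction with at least 30 sequences, up to 4 called members per list or else the most abundant ones, the Aux/IAA and ARF members the title points to, and the most abundant gene models. As no gene model was called, most genes named below are list members on the deposited sheets or genes with large deposited ratios, chosen after their values were seen. Gene names are the authors' descriptions. None of the identifiers matched the reference gene table (0 matches), so no coordinates or builds are given.

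Alternatives covered scaling, the count minimum, the pseudocount, the thresholds, the spread, the unit and, for the sheets, how copies of a gene were counted. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures from matplotlib 3.10.9.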

Results

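Transcripts were compared between the central and the lateral pedicel of apple clusters in Saika, a cultivar that sheds fruits of its own accord. The series title ties early fruit drop to a cascade of the auxin repressor IAA14/SLR and the auxin response factor ARF7. The central library held 18483 mapped sequences on 13544 gene models and the lateral library 18368 on 13457. Of the sequences, 89.3% in the central and 89.4% in the lateral library mapped uniquely. In the central library 72.9% of detected gene models, and in the lateral library 73.1%, had exactly 1 sequence. The highest count was 10 in the central library, for MDP0000241462, a share of 0.0541% (95% exact interval 0.0259% to 0.0995%).

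**Figure D1:**
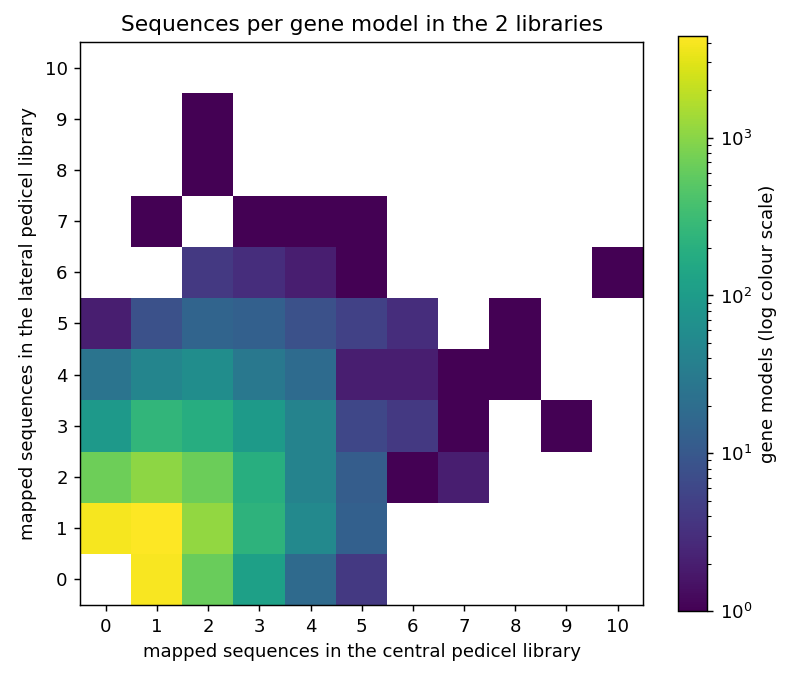
Mapped sequences per gene model in the central (horizontal axis) and lateral (vertical axis) pedicel library, with the number of gene models on a log colour scale and gene models without any sequence left out. Most gene models lie at 0 or 1 sequence per library, and 4417 have 1 in each.

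The first comparison asked which gene models differed between the 2 libraries. The widest gaps among gene models with at least 10 sequences were those of MDP0000271642, an Octicosapeptide/Phox/Bem1p domain protein with 2 central and 9 lateral sequences, and MDP0000165286, a Toll-Interleukin receptor domain protein with 2 and 8. In the other direction, MDP0000295807 had 9 central and 3 lateral sequences. A no apical meristem (NAM) protein, MDP0000180046, had 6 and 5, and a Cupredoxin, MDP0000283457, also had 6 and 5. None of the 24 gene models was called by the Fisher exact test. For MDP0000271642 the log2 ratio was 1.94 with an unadjusted p of 0.0380 and an adjusted p of 0.775. It was the 1 gene model with an unadjusted p under 0.05, and edgeR's negative binomial exact test gave 0 such gene models. Without a minimum count, 0 of 18337 gene models were called and 4 had an unadjusted p under 0.05. The authors' deposited table calls 12403 gene models at an FDR under 0.05 by Kal's Z-test, 6173 of them higher in the lateral and 6230 higher in the central library.

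The second comparison concerned the 35 fixed gene lists in the whole table. The words fixed for the lists found no member with at least 10 sequences. The whole table is annotated mostly by protein domain, so the words missed family members there, among them the NAM proteins, of the NAC family, with 22 central and 20 lateral sequences in all. Summed over members, heat shock proteins held 140 central and 129 lateral sequences, ribosomal proteins 157 and 144, and genes of peroxidases, glutathione S-transferases and related redox proteins 165 and 168. Defence genes held 83 and 76, cellulases, expansins and XTHs 26 and 23, and polygalacturonases and other pectinases 27 and 20. Markers of chloroplast-bearing cells held 8 and 11 sequences, and epidermis and cuticle genes 33 and 42. None of these sums differed between the libraries by the Fisher exact test, and the adjusted p was 1 for every list with a sequence. The counted sequences are contigs, so similar counts or sums do not show that expression was alike. Over lists with at least 5 detected members, the Aux/IAA repressors lay farthest above the random lists, with a median log2 ratio of 1.17 at percentile 86.6 over 10 gene models. With the 2 Aux/IAA genes that only the deposited sheets annotate as such, the median was 0.38 at percentile 46.1.

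The third comparison used the authors' deposited sheets of differing genes, 844 entries headed CP and 741 headed LP. All FDR values given for these entries were deposited by the authors on the sheets and are not taken from the whole table's Kal's Z-test columns. The headers name NOISeq, and how these p-values and FDR values were computed is not known here. The ratios given for these entries are the log2 ratios that the authors deposited separately, with the sign as deposited. That sign was positive for all 78 CP genes and negative for all 113 LP genes with a ratio. It therefore opposes the sheet names if read as lateral over central, and is not used here as a direction. The lists were chosen by the authors on these same libraries, so the counts below are not independent evidence of a direction. They are the entries whose annotation held the words fixed for a list, so other genes of the same function can be missing and genes of another function included. Genes of chloroplast-bearing cells had 7 entries on the CP sheet and 20 on the LP sheet, at percentile 99.8 of random draws. Entries of the list on the LP sheet included light-harvesting complex II subunit B1 (deposited log2 ratios -2.18 and -2.10), rubisco activase, ferredoxin-NADP(+)-oxidoreductase 1 and 2, and photosystem I subunits G and O. Entries with the gene ontology term photosynthesis, counted apart from the list, numbered 7 and 9, at percentile 77.2. Defence genes had 10 CP and 2 LP entries, at percentile 1.74, with a chitinase, beta-1,3-glucanase 3, a thaumatin-like protein and 3 dirigent-like proteins on the CP sheet. Redox genes had 18 CP and 6 LP entries, at percentile 1.59, among them glutathione peroxidase 2, ascorbate peroxidase 3 on the CP sheet, and glutathione peroxidase 7 and thylakoidal ascorbate peroxidase on the LP sheet. Thioredoxin M-type 4 had 1 entry on each sheet, the CP entry with a deposited log2 ratio of 2.39. Of the 18, 3 are copies of the translation elongation factor EF1B, also counted among ribosomal proteins, and without them the redox list lay at percentile 4.79. The broader gene ontology term oxidoreductase activity leaned the other way, with 23 CP and 46 LP entries. With genes lacking any mapped sequence left out, defence and redox genes moved to percentiles 7.29 and 17.1. Heat shock proteins, fixed as a sign of RNA handling, had 12 CP and 4 LP entries at percentile 4.46, beside these CP groups, and 10 and 2 at percentile 2.00 with genes lacking a sequence left out. Of 31 lists with entries, 3 lay outside the central 95% of random draws, where chance gives up to 1.55.

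**Figure D2:**
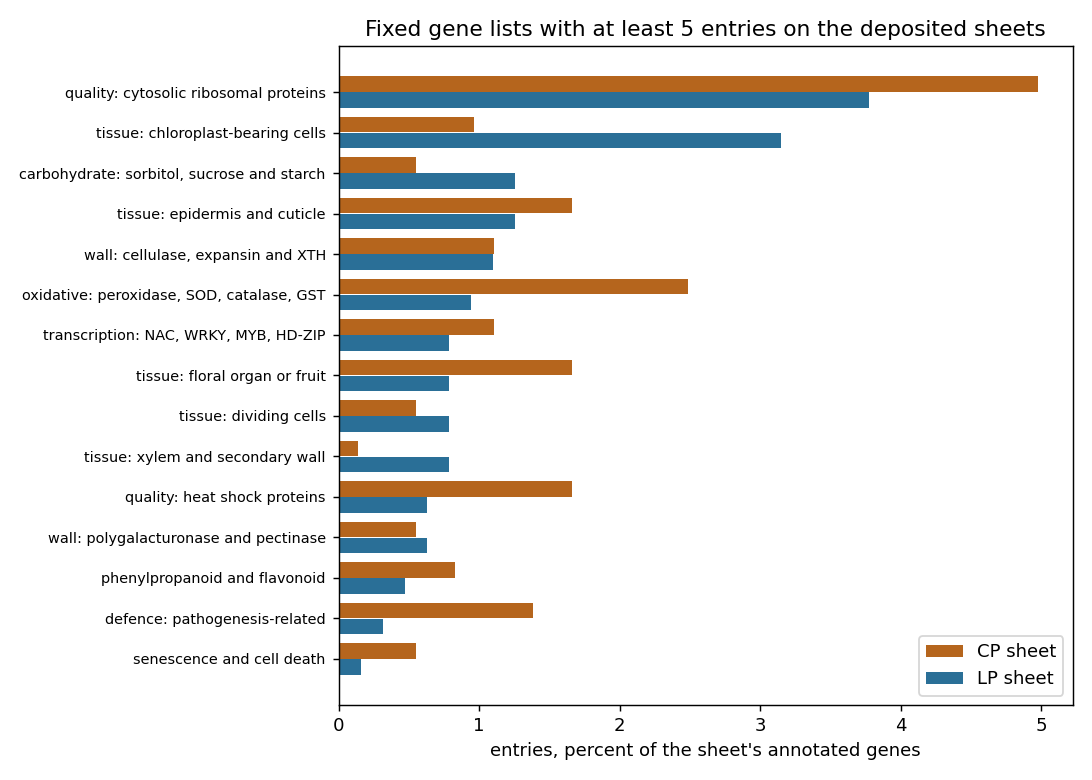
Entries of the fixed gene lists with at least 5 entries, in percent of the annotated genes of each deposited sheet (CP, 724 genes; LP, 636 genes); bars start at 0. Chloroplast genes made up 0.967% of the CP and 3.14% of the LP sheet, and redox genes 2.49% and 0.943%.

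Hormone genes were split between the sheets in small numbers. The words searched for ERF transcription factors found 4 entries on the CP sheet, 3 of them annotated as the ethylene-responsive element binding protein and 1 as ERF5. The CP sheet also held EIN3-binding F box protein 1, which targets the ethylene regulator EIN3 for breakdown. The ethylene-forming enzyme, which makes ethylene from ACC, was on the LP sheet. The words searched for jasmonate genes found 3 CP entries, namely allene oxide cyclase 4 (deposited log2 ratio 3.66), lipoxygenase 2 and jasmonate-zim-domain protein 1. They did not find OPC-8:0 CoA ligase1, a gene of jasmonate synthesis on the LP sheet. For allene oxide cyclase 4 the whole table has 0 central and 2 lateral sequences. Of the auxin-responsive genes, 2 SAUR-like genes were on the CP sheet and 2 GH3 family genes, both matched to the Arabidopsis gene of the jasmonate-conjugating enzyme JAR1, on the LP sheet. The 3 LOB domain genes, numbers 25, 38 and 21, were on the CP sheet. Response regulator 9 had 2 entries on the CP sheet, and cytokinin response factor 4 was on the LP sheet (deposited log2 ratio -4.93), and the whole table gives it an ERF-type DNA-binding domain. Of the KNOX homeobox genes, which act in meristems and organ development, KNOTTED1-like homeobox gene 3 was on the CP sheet (deposited log2 ratio 2.13) and a KNOTTED-like gene on the LP sheet.

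Wall genes were on both sheets. Cellulases, expansins and XTHs had 8 CP and 7 LP entries, and pectin-degrading enzymes and their relatives 4 and 4. Expansin A8 had 1 entry on the CP sheet and 2 on the LP sheet, and expansin A4 had 2 and 1. XTH 5 was on the LP sheet (deposited log2 ratio -2.68). Xylem and secondary wall genes had 1 CP entry, laccase 14, and 5 LP entries at percentile 95.6, namely FASCICLIN-like arabinogalactan proteins 2, 11 and 12, cinnamyl alcohol dehydrogenase 9 and vascular related NAC-domain protein 1. Carbohydrate genes had 4 CP and 8 LP entries, at percentile 90.8, and the LP entries included cell wall invertase 4 (deposited log2 ratio -2.42) and sugar transporter 1 (-1.98). With a deposited FDR under 1e-06 they were 1 and 7, at percentile 98.1, and with genes lacking a sequence left out 3 and 6, at percentile 86.8.

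Ribosomal proteins had 36 CP and 24 LP entries, some of them plastid or mitochondrial. Epidermis and cuticle genes had 12 and 8, and floral or fruit genes 12 and 5. The 2 lists share lipid-transfer proteins, 11 of which made up most of the CP entries of both. Dividing cell genes had 4 CP entries, histones and proliferating cell nuclear antigen 2, and 5 LP entries that included B-type cyclins. The words searched for phenylpropanoid genes found 6 CP and 3 LP entries. They missed the entry enzymes of the pathway, namely phenylalanine ammonia-lyase 1, with 1 entry on each sheet (deposited log2 ratios 3.66 and -2.31), and cinnamate 4-hydroxylase, with 2 CP entries. The words for NAC, WRKY, MYB and HD-ZIP factors found 8 and 5. They found no NAC gene, although each sheet held 1 annotated as a NAC domain regulator and the LP sheet also held vascular related NAC-domain protein 1. Among the 8, 1 is Target of Myb protein 1, a trafficking protein. Counted in the same way, senescence genes had 4 and 1, brassinosteroid genes 2 and 0, phloem genes 1 and 2, and pollen genes 1 and 2. The words for organelle transcripts found 1 and 2 entries, a cytochrome b6f subunit (petM) on each sheet and a tRNA/rRNA methyltransferase on the LP sheet, which are products of nuclear genes. Abscisic acid, gibberellin and aquaporin or dehydration genes each had 0 and 1.

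Direction was then compared between the sheets and the whole table. On the CP sheet, 287 entries had more sequences in the central and 137 more in the lateral library. On the LP sheet, 116 had more in the central and 233 more in the lateral library. The remaining entries were equal, and 190 CP and 159 LP entries had no sequence in either library. The authors' deposited table of log2 ratios is positive for all of its 78 CP genes and negative for all of its 113 LP genes, although its first line gives the direction as lateral over central. The ratios are printed here with the sign as deposited.

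**Figure D3:**
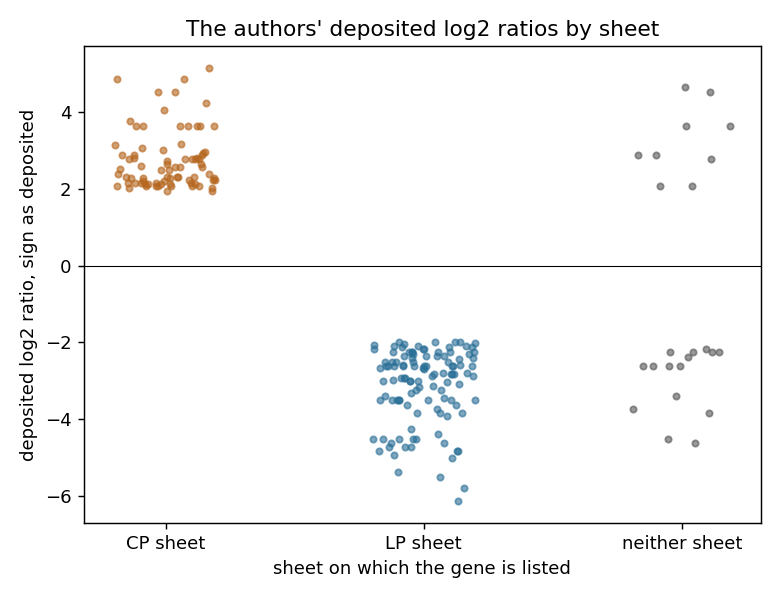
The authors' deposited log2 ratios (vertical axis, sign as deposited) for genes on the CP sheet, the LP sheet and neither sheet; each point is 1 gene, and the horizontal spread within a group carries no value. The 78 CP genes lie between 1.95 and 5.16 and the 113 LP genes between -6.14 and -1.98.

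The largest deposited log2 ratios on the CP sheet belonged to phospholipase D delta (5.16), a CCT motif protein and an Immunoglobulin E-set protein (both 4.88). Sulfate transporter 3;1 had 2 entries, at 4.07 and 3.03. On the LP sheet they belonged to OPC-8:0 CoA ligase1 (-6.14), which acts in jasmonate synthesis, sterol-4alpha-methyl oxidase 1-1 (-5.79) and a RING/U-box protein (-5.51). In the whole table these genes had at most 2 sequences in a library. Phospholipase D delta had no sequence, and sterol-4alpha-methyl oxidase 1-1 and the sulfate transporter entry at 4.07 had 1 in each library. The others had more in the library that their sheet is named for.

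The last comparison took up the Aux/IAA and ARF genes that the title points to. The homolog of IAA14, an Aux/IAA repressor, is MDP0000124810, and it was on the LP sheet with a deposited FDR of 1.18e-10. In the whole table it had 2 central and 1 lateral sequences, a log2 ratio of -0.73. Another Aux/IAA gene, MDP0000945260, was on the CP sheet and also had 2 and 1. Of 28 gene models annotated as AUX/IAA protein, 10 had a sequence, 5 central and 9 lateral sequences in all (Fisher exact p = 0.300). With MDP0000124810 and MDP0000945260, which that annotation leaves out, the 12 genes had 9 central and 11 lateral sequences (Fisher exact p = 0.663). The single gene model annotated as an auxin response factor, MDP0000485205, had 1 sequence in each library, and neither sheet held a homolog of ARF7 or ARF19 (0 entries). The whole table is annotated mostly by protein domain, so other ARF genes, a homolog of ARF7 among them, could have been missed there. The ARF family as a whole was therefore not examined. None of the 13 family members was called, adjusted over the list alone or over all gene models, and the smallest unadjusted p was 0.498. Each had at most 2 sequences in a library, too few for the Fisher exact test to call any at whatever split. The test therefore does not bear on whether these genes differed. The counted sequences are contigs per the file header, and a contig count does not give the number of reads behind it.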

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

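The tests in this part were chosen after the result was seen. The deposited ratios include 24 genes that are on neither sheet, a signal outside the comparisons of the report. Of them, 9 were positive and 15 negative, from -4.63 to 4.66. They include MDP0000320717, a Kinesin-related protein (-4.63), and MDP0000718381, a P-type ATPase (4.66).

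The deposited ratios carry the sign opposite to the direction named in their first line, if the sheet names are taken as they stand. The whole table argues against that stated direction, since 30% of the genes with a positive ratio and unequal counts had more sequences in the lateral library, below the 40% to 60% of shuffled signs, and without the genes on neither sheet the share was 35.7%, below 40.5% to 64.3%. Of all positive-ratio genes with unequal counts, 70% had more in the central library, consistent with ratios of central over lateral. An exchange of the sheet names is argued against by the CP entries with unequal counts, of which 32.3% had more in the lateral library, against 44.8% to 51.2% for shuffled names. No biological explanation was tested for a sign.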

How the results depend on the processing

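The percentile settings, the widened Aux/IAA list, the genes on a sheet only, the deposited Z-test and the negative binomial test of the Aux/IAA and ARF genes were chosen after seeing the data, and the others before. Of 48 alternative values, 35 were the same, some of them because the setting could not change the value, and 0 reversed. The count of called gene models stayed at 0 in all planned tests. Scaling, the pseudocount, the fold threshold and a stricter adjusted p could not raise it, since the smallest adjusted p of the Fisher exact test was 0.775. In the authors' normalized values, taken without a test, 5 of the 24 gene models differed at least 2-fold. The deposited Z-test on RPKM called 12403 over all gene models, and its construction, which took RPKM as counts, shows the cause. By the words fixed for them, without a minimum count 27 lists had a member, and with identical annotations added up 16 had one, since the 10-sequence minimum leaves none. No entry of either sheet (0 of CP, 0 of LP) had 10 sequences, so at that minimum the test on counts was run on none. In the direction of the sheet name were 287 CP and 233 LP entries. The lists of defence genes (percentile 7.29 without genes lacking a sequence) and redox genes (17.1 in that setting, 3.05 with each Arabidopsis match counted once, 4.79 without EF1B) returned to within the central 95% of random draws, and the cause was not tested. Heat shock proteins left it without genes lacking a sequence (2.00), and carbohydrate genes (90.8) left it at an FDR under 1e-06 (98.1). The fixed list of chloroplast genes stayed outside it in these settings, while the photosynthesis term lay inside (77.2). Scaling and pseudocount cannot change how many lists have a member. A minimum of 30 sequences left no gene model, so it gave no value. None of the Aux/IAA and ARF genes had 10 sequences. Without that minimum, the negative binomial exact test with an assumed variation of 0.4 called 0 of the 13, which had too few sequences for any call. The median log2 ratio of the Aux/IAA list, 1.17, was 0.38 with the sheet genes. No paired analysis was possible because each group has 1 library, and for that reason no library could be left out. How far depth limits the counts is not known, since the simulated sequences were independent and the counted ones were contigs.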

Other observations

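The comparisons of functions, of shared matches between sheets and of whole-number ratios in this part were chosen after the data were seen, except the test on uniquely mapped sequences, which was written down before its result. The words searched for chlorophyll and heme metabolism found 6 LP and 0 CP entries. They were glutamyl-tRNA reductase (deposited log2 ratio -2.71), glutamate-1-semialdehyde-2,1-aminomutase (-4.51), ferrochelatase 2 (-2.63), uroporphyrinogen decarboxylase, the CHLH subunit of magnesium chelatase and chlorophyllase 1. They stand beside the 20 LP and 7 CP entries of chloroplast-bearing cells. Fatty acid desaturases had 7 LP entries and 1 CP entry. Fatty acid desaturase 8 had 1 entry on each sheet. Histones had 8 CP and 0 LP entries, proteasome proteins 9 and 4, and bHLH proteins 8 and 2. Sulfate transporters had 3 CP and 0 LP entries. Phosphate transporter 1;7 and nicotianamine synthase 3 (deposited log2 ratio 3.19) were on the CP sheet, and glucose-6-phosphate/phosphate translocator 2 (-2.25) was on the LP sheet. These groups were picked because they looked uneven.

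Of 50 gene ontology terms with at least 10 entries, 6 lay outside the central 95% of random draws, where chance gives up to 2.5. Oxidoreductase activity, opposite to the fixed redox list (18 and 6), had 23 CP and 46 LP entries, lipid metabolic process 3 and 16, and metabolic process 25 and 37. Regulation of transcription had 37 and 14, DNA binding 38 and 17, and heme binding 12 and 3. Photosynthesis, with 7 and 9, lay within them at percentile 77.2, or 67.4 with each match counted once. With each Arabidopsis match counted once, 5 of the terms lay outside, and heme binding was within at percentile 2.79. Oxidoreductase activity then had 22 and 40, lipid metabolic process 3 and 14, and regulation of transcription 30 and 14, at percentiles 99.8, 99.8 and 1.89.

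The deposited Z-test called 12403 gene models, including 8062 of the 8067 with a single sequence in both libraries together, while the Fisher exact test and the same Z-test, both on the counts, called 0 (51 had an unadjusted p under 0.05 in the latter). The deposited Z statistic was recovered from RPKM taken as counts for 100% of gene models with a sequence, within 1e-06, so the calls come from a test that took RPKM for counts. Independent reads are argued against, since 76.7% of gene models with 2 sequences had 1 in each library, where independent reads give at most 1 in 2. Assembled contigs, which the file header names, could give such a share, since many transcripts would then be counted once in each library. Not every gene model was counted once, as counts reached 10 in the central library. No biological explanation was tested.

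The deposited ratios are not made from these counts. All 215 equal a ratio of whole numbers up to 80 times 1 constant (0.07 on the log2 scale), within 1e-05, the best of 348 constants tried. The same search on values with added noise gave 6. In all 215 the larger whole number exceeds the gene's count in the table.

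Genes with the same Arabidopsis match tended to be on the same sheet. Of 133 matches with several genes, 46 were on both sheets, fewer than the mean of 69.8 in 10000 shufflings (range 45 to 90). These values cannot decide whether reads were split at random between near-identical gene models. Copies that share the reads of a differing gene would take its ratio and could fall on the same sheet too. Among genes whose mapped sequences were all unique, 21 of 63 were on both sheets against a mean of 32.1, and 40 of 10000 shufflings gave as few. Uniqueness was known for the table's sequences and not for the reads behind the sheets. The tendency thus held for genes with unique sequences in the table. It cannot decide whether reads counted in several gene models were the cause. Copies that are regulated alike are another possible explanation, as a hypothesis that was not tested.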
